A study of Mus musculus with 18 samples.

How the data were processed

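The series holds 18 libraries of C3H10T1/2 cells or tumors derived from them, sequenced as TruSeq RNA-seq libraries made from Trizol-extracted RNA, per the labels' protocols. The labels gave 6 groups: H3.3 wild-type cells (n = 2), H3.3K36M cells (n = 2), H3.1K36M cells (n = 2), control siRNA cells (n = 3), HMT siRNA cells (n = 3) and H3.3K36M tumors (n = 6). Cells were at passage 10 to 15, per the labels, and 2000000 cells were injected into mice of 6 to 8 weeks. Reads were aligned with Bowtie 1.0.0 to the mm9 build and expression was estimated with RSEM 1.2.12, per the submitters' processing notes.

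The authors deposited 3 tables of 20325 genes, with 26 columns in all, that hold a signal made of estimated counts divided by a factor for each library, with the libraries of a table brought to a common level by the authors (median normalisation, as the deposited files name it). The tables were scaled separately, so values of the same library differ between them by a constant and comparisons stay within a table. Only the levels of Cdkn2a, Cdkn2b and Mtap, and H3.1K36M against control siRNA cells in 1 test on drift, were brought to a common scale, through the mean ratio of the 4 libraries that both tables hold (1.318 to 1.354 per library). Every deposited signal value was a multiple of 0.01 of 1 step per library, and the steps gave depths of 13993307 to 56041798 estimated reads. Only 35.2 to 56.1% of values came out as whole counts of that step (tolerance 0.01), so whole reads are not claimed and the planned count test was not used. The plan had set that test for tables of raw or expected counts and named no condition on whole reads. Among genes with 1 to 20 estimated reads, whole counts made up 76.8 to 79.1% in the H3.3 wild-type and H3.3K36M libraries and 84.2 to 86.8% in the other 14; the labels give no batch. Comparisons of H3.1K36M cells, tumors or siRNA cells with H3.3 libraries cross this line, the last of them wherever control siRNA cells serve as the reference. H3.3K36M against wild-type cells and HMT against control siRNA cells do not cross it. Values that stand for a few estimated reads are imprecise at this depth. The reference annotation at hand is of another build than mm9, so no coordinates are given. It served only to look up names: 18340 of the symbols matched GENCODE M21 and 20173 matched RefSeq names or synonyms.

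Values were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with eBayes using trend and robust options, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. Genes tested had a value of at least 10 in as many libraries of the fit as the smaller group holds. H3.3K36M and H3.3 wild-type cells were compared in their own table. HMT and control siRNA cells, and the difference between the mutant and the knockdown response, came from 1 fit of the 10 cultured libraries of the siRNA table. H3.1K36M cells were compared with both other lines in 1 fit of 6 cultured libraries, and tumors with H3.3K36M cells in a fit of 8 libraries. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

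Gene lists fixed before the data were examined covered H3K36 methyltransferases, H3K36 demethylases and readers, Polycomb complexes, Hox genes, developmental transcription factors, Wnt genes, BMP and TGF-beta signalling, adipocyte, chondrocyte (called cartilage genes here) and osteoblast genes, smooth and skeletal muscle, extracellular matrix, cell cycle, p53 targets and cell cycle inhibitors, interferon-stimulated genes, cytokines and chemokines, glycolysis and hypoxia, ATF4 and unfolded protein response, cholesterol synthesis, imprinted and germline genes, markers of macrophages, endothelium, pericytes, red cells, neutrophils, lymphocytes and NK cells, mast cells, keratinocytes and Schwann cells, replication-dependent histones and ribosomal proteins. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation; lists with under 4 tested members were not tested. With the estimated correlation the cartilage list held in the HMT siRNA comparison and in the difference of responses, and no other list held. That form of the test also uses the residual degrees of freedom of the fit, in place of a number set by the genes tested. These were 2 for H3.3K36M, 3 for both H3.1K36M comparisons and 6 for the others. A list can therefore fail it without correlated genes. The Wnt list of H3.3K36M cells had an estimated correlation of -0.0455, below the preset, yet its camera p went from 0.0121 to 0.11. Where a count adjusted over the list alone is not given beside a list in the text, it was within 3 genes of that over all genes, except for the histone list in the difference of responses (0 against 5). The median, mean and test of each list past the threshold had 1 sign.

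Named genes followed a rule set before the data were examined: Nsd1, Whsc1, Setd2, H3f3a and H3f3b always; the 8 largest changes in each direction (6 for the difference, 4 for H3.1K36M against wild type) with a mean of at least 50 and no overlap between libraries; and up to 3 members with the smallest adjusted p from the fat, cartilage, bone, Hox, developmental and Wnt lists, from the 4 other lists with the smallest p and, in tumors, from the host marker lists. Other genes were chosen after their values were seen, such as Sox9, the HoxB genes as a set, Ccl2, Ccl7, Il33, Lgr5, Axin2, Mpeg1 and Cd74 in H3.3K36M cells, Dlk1 and Mest in HMT siRNA cells, the C1q genes in H3.1K36M cells, and Egln3, Slc2a3, Car9, Krt5, Ckm and Csn2 in tumors. The rule itself named Sox9 in HMT siRNA cells, Dlk1 in H3.1K36M against H3.3K36M cells and Axin2 and the C1q genes in tumors. Its condition of no overlap between libraries was not checked for the genes of the difference. Shared reads make Sprr2, Prl2c, Gzmd, Gzmg, Rps27, Tgoln2, hemoglobin, H2-Q7 and histone genes uncertain.

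Replicate pairs were checked with a chi-square test of estimated counts over genes counted whole in both. Over these genes cultured pairs stood near sampling noise (chi-square of 1.1 per gene for wild-type and H3.1K36M cells, 1.24 for H3.3K36M cells and up to 1.89 for control siRNA cells), and tumor pairs at 6.91 to 34.6. Over all genes the values were 3.72 for wild-type, 7.48 for H3.3K36M, 1.8 for H3.1K36M, up to 2.94 for HMT siRNA and up to 4.34 for control siRNA cells. All libraries were counted. Each pair differed by more than sampling noise, but that excess may be technical and does not show separate cultures. The tests were tried on simulated data with known changes. These were whole counts with 1 dispersion for all genes of a comparison and 50 changed genes of each size. The real values hold shared reads and most genes were called in them, so the rates below may not carry over to the real data. In the H3.3K36M comparison 100% of 2-fold and 74% of 1.2-fold changes were recovered and 4 of 12318 unchanged genes were called. For HMT siRNA these were 100%, 64% and 23 of 12137 genes; for H3.1K36M, 94%, 68% and 9 of 12444; for tumors, 94%, 6% and 9 of 13210. Alternatives tried were pseudocounts of 0.5 and 8, no filter, TMM scaling, quantile normalisation, a replicate block, eBayes without trend and robust options, each library left out, other sets of libraries in the fit and array weights. Added after the data were seen were voom on the estimated counts, control siRNA cells as the reference for H3.3K36M cells, the counts at 2-fold, 1 wild-type library for each mutant line, the macrophage list of H3.1K36M cells less the C1q genes, and list tests without each compared library.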

Results

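RNA sequencing measured gene expression in cultured C3H10T1/2 cells, a multipotent mesenchymal line from C3H mouse embryos that can be driven toward fat, cartilage and bone, and in tumors grown from 1 of its derivatives. The 12 cultured libraries included cells stably expressing tagged wild-type histone H3.3 (n = 2), H3.3 with a lysine-to-methionine substitution at the K36 position (H3.3K36M, n = 2) or H3.1K36M (n = 2). The others were cells given a scramble siRNA (n = 3) and cells given siRNAs against the H3K36 methyltransferases Nsd1, Nsd2 (listed as Whsc1) and Setd2 (HMT siRNA, n = 3). The other 6 libraries were tumors that arose 5 to 6 weeks after subcutaneous injection of 2000000 H3.3K36M cells into immunodeficient mice. Depth ranged from 13993307 to 56041798 estimated reads per library. Levels below are normalised estimated counts, given as mean ± SD, and are compared within a table unless a common scale is named. A ± after a log2 fold change is its standard error (SE). Each histone line is a single line. The labels do not say that libraries of a group were separate cultures or that each tumor came from its own mouse. The p-values therefore measure the spread between these libraries, which may be technical.

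H3.3K36M cells were compared with H3.3 wild-type cells to find the genes that differ when H3.3 carries the K36M substitution. The clearest group was cartilage genes, of which 23 of 24 tested fell and none rose. Col2a1, the type II collagen of cartilage, fell from 97980 ± 2054 to 8468 ± 428 (log2 fold change -3.53 ± 0.04 SE, adjusted p = 6.76e-14), and Col11a1 fell from 49932 ± 914 to 3728 ± 168 (log2 -3.74). Acan, which encodes the proteoglycan aggrecan, fell from 568 ± 5.53 to 1.15 ± 1.62, and Sox6, a transcription factor of chondrocyte differentiation, fell from 3130 ± 199 to 27.9 ± 2.98. Sox9, the master regulator of the lineage, changed by log2 -2.79. Cytl1 fell from 5419 ± 116 to 12.9 ± 1.97. The camera test gave adjusted p = 1.48e-12 for the list, and adjusted p = 0.541 with an estimated correlation.

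Matrix genes followed in part, with 42 of 60 lower and 16 higher (adjusted p = 4.3e-05, and adjusted p = 0.541 with an estimated correlation). Elastin (Eln) fell from 34000 ± 1549 to 90.3 ± 15.3, Col8a1 changed by log2 -4.20 and Thbs1 by log2 -3.48, while Thbs2 rose from 620 ± 1.86 to 7336 ± 28.3. Replication-dependent histone genes were lower for 20 of 36 and higher for 2 (adjusted p = 0.00178, and adjusted p = 0.541 with an estimated correlation). Hist1h1c changed by log2 -1.76, Hist1h2bc by -1.56 and Hist1h4i by -1.66. These histone genes have near-identical copies, so their values are uncertain. Among fat genes 11 of 22 fell and 6 rose (adjusted p = 0.208). Cebpa, an early adipocyte regulator, changed by log2 -2.52 ± 0.06 and Dgat2 by -3.35 ± 0.08, while Angptl4 rose by 4.34 ± 0.09. Among bone genes 13 of 21 fell and 7 rose (adjusted p = 0.212). Tnfrsf11b, the decoy receptor for RANKL, was at log2 -5.05, Postn at -3.40 and Spp1, which encodes osteopontin, at 2.09.

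Cytokine and chemokine genes rose for 17 of 26 and fell for 3 (adjusted p = 0.00824, and adjusted p = 0.541 with an estimated correlation; 21 changed when adjusted over the list alone, against 20 over all genes tested). Ccl2 changed by log2 5.07, Ccl7 by 4.73 and Il33 by 4.02. Wnt genes rose for 15 of 22 and fell for 4 (adjusted p = 0.035, and adjusted p = 0.541 with an estimated correlation). Lgr5 and Axin2, both Wnt target genes, changed by log2 6.14 and 4.51, and Notum, a secreted Wnt antagonist, rose from 68.2 ± 7.34 to 1390 ± 77.4. The antagonist Sfrp2 fell from 5971 ± 51.3 to 12.8 ± 4.38, and Rspo2 changed by log2 -2.98 and Tcf7 by -2.89. Smooth muscle and contractile genes rose for 9 of 14 and fell for 3. Macrophage markers rose for 7 of 8, and for 4 of 8 after quantile normalisation, among them Mpeg1 and Cd74 (log2 3.85 and 3.56). Each of these 2 lists had adjusted p = 0.035, and adjusted p = 0.541 with an estimated correlation. The Wnt, smooth muscle and macrophage lists no longer passed without either H3.3K36M library (adjusted p = 0.0974 to 0.18).

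Cell cycle genes rose in 48 of 58 cases and fell in 3, by a small amount (median log2 0.32; adjusted p = 6.74e-07, and adjusted p = 0.615 with an estimated correlation). Mcm2 was at 1.14, Uhrf1 at 1.00 and Top2a at 0.89. Genes of the ATF4 stress response and the unfolded protein response rose in 21 of 31 cases and fell in 4 (adjusted p = 0.00181, and adjusted p = 0.615 with an estimated correlation). Ribosomal protein genes rose for 39 of 40 (median log2 0.44; adjusted p = 6.41e-10, and adjusted p = 0.541 with an estimated correlation). Rpl23 was at 0.70, Rps20 at 0.73 and Rplp0 at 0.66. Ribosomal protein genes held 4.28% and 4.35% of the estimated reads of the wild-type libraries, 5.84% and 5.99% in H3.3K36M, and 5.94 to 6.57% in control siRNA cells. Set against control siRNA cells, whose libraries differ from the H3.3 libraries in their share of whole counts, Rps20 was at log2 -0.15 and Rplp0 at 0.02, and Hist1h1c and Hist1h4i were at 0.15 and 1.61.

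Of the Hox genes 8 of 18 rose and 7 fell (adjusted p = 0.947; list median log2 -0.03 and mean 1.46; 8 and 8 after quantile normalisation). All 7 tested HoxB genes rose, a grouping made after the values were seen, with Hoxb9 from 3.47 ± 1.08 to 677 ± 41.5, while Hoxc13 fell from 599 ± 45.2 to 32.5 ± 3.51 and Hoxa3 from 1074 ± 3.84 to 311 ± 23.5. Hoxc13 had log2 3.25 against control siRNA cells. Developmental transcription factors, chosen as typical Polycomb targets, rose for 24 and fell for 21 of 54 (adjusted p = 0.947; 19 and 21 after quantile normalisation), with Osr2 at log2 3.54 and Meis1 at 1.44. Interferon-stimulated genes rose for 21 and fell for 8 of 39, and skeletal muscle genes rose for 7 of 11 (adjusted p = 0.0633 for each). Without a wild-type library the former passed (0.0313 and 0.0324), and the latter without replicate 2 (0.0285). After quantile normalisation 5 skeletal muscle genes were higher and 2 lower. BMP and TGF-beta genes rose for 11 and fell for 16 of 30 (adjusted p = 0.413). The p53 targets and cell cycle inhibitors rose for 12 and fell for 9 of 21 (adjusted p = 0.88). Imprinted genes rose for 7 and fell for 10 of 19 (adjusted p = 0.846). Glycolysis and hypoxia genes rose for 14 and fell for 13 of 35 (14 and 14 after quantile normalisation), and Polycomb complex genes rose for 8 and fell for 8 of 20. Germline genes rose for 2 and fell for 3 of 8 (adjusted p = 0.947 for each of these lists). H3K36 demethylases and readers rose for 3 and fell for 9 of 16 (adjusted p = 0.212). Cholesterol synthesis genes rose for 4 and fell for 12 of 24 (adjusted p = 0.329).

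The largest rises were Stra6, the retinol transporter, from 6.05 ± 2.58 to 1813 ± 48.3, Fcgbp from 0.656 ± 0.928 to 295 ± 6.54. Others were F13a1 from 0.656 to 293 ± 8.42, Eda to 240 ± 9.62 and Apob to 236 ± 8.51. Sprr2a1 and Sprr2a2 (both from 40.4 to 10656) and Prl2c3 share reads with near copies and are uncertain. The largest falls included Cmtm5, at 569 ± 23.9 in wild-type cells and listed at 0 in H3.3K36M cells, Angptl1 (log2 -8.31), C1qtnf3 (-7.74) and G0s2 (-7.68). Among the genes named in every comparison, Whsc1 rose by log2 1.06 ± 0.04, Setd2 changed by -0.24 ± 0.04, H3f3a by -0.79 ± 0.04 and H3f3b by -0.27 ± 0.04. Nsd1 did not pass the test (0.09 ± 0.04, adjusted p = 0.0539). Setd2 did not pass against control siRNA cells (-0.06), and Nsd1 and H3f3b stood at -0.05 and 0.22 there. In all, 9878 of 13232 genes tested changed (5106 higher, 4772 lower), 2816 of them by at least 2-fold (1690 higher, 1126 lower). After quantile normalisation the at least 2-fold genes were 1395 higher and 1425 lower, without the excess of higher genes. With no filter on low values they were 2566 higher and 1273 lower, with a larger excess.

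**Figure D1:**
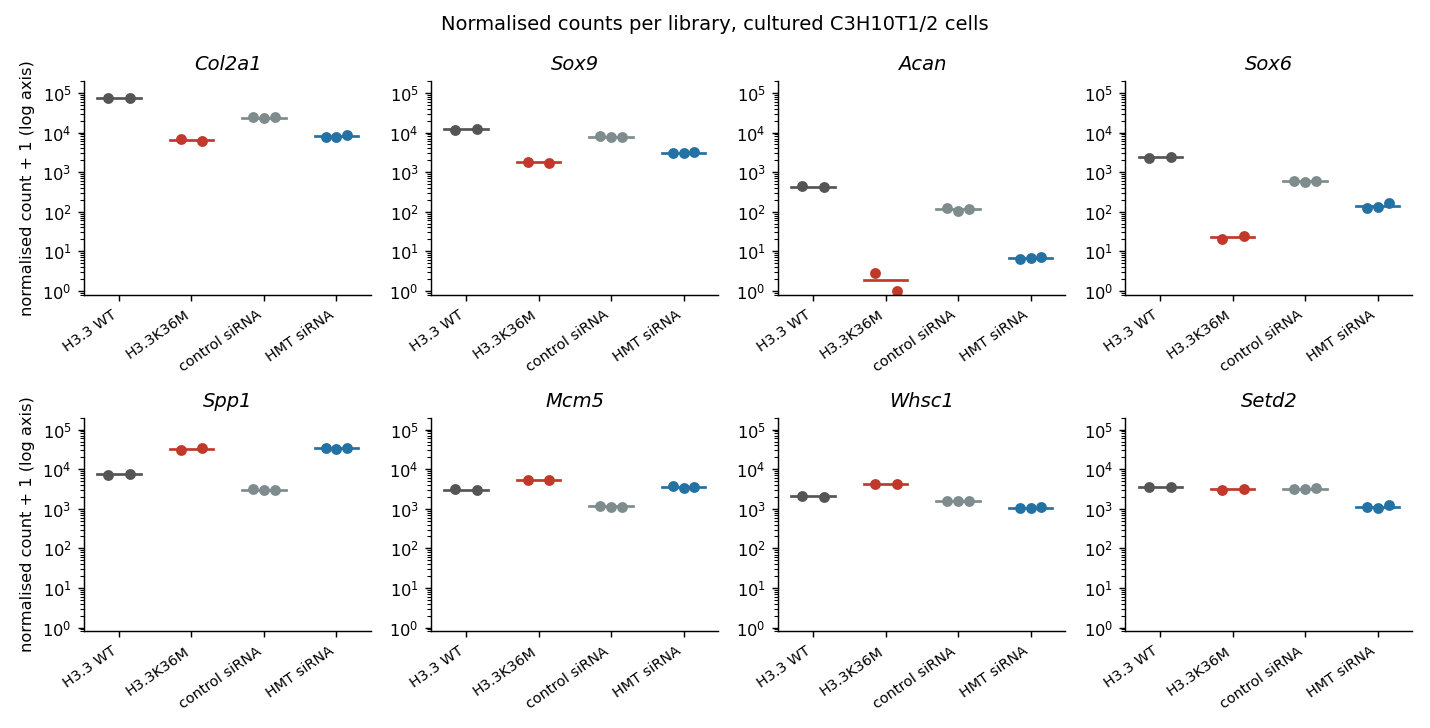
Normalised counts plus 1 (log axis) of 8 genes in each cultured library of the siRNA table. Points are libraries and lines are group means; Col2a1, Sox9, Acan and Sox6 were lower in H3.3K36M than in wild-type cells and lower in HMT siRNA than in control siRNA cells, Spp1 and Mcm5 were higher in both, and Setd2 was lowest in HMT siRNA cells.

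HMT siRNA cells were compared with control siRNA cells to find the genes that change when the enzymes that methylate H3K36 are reduced. Setd2 transcript fell from 3247 ± 145 to 1134 ± 82.0 (log2 -1.52 ± 0.05), Whsc1 from 1588 ± 21.3 to 1059 ± 54.7 (-0.59 ± 0.04) and Nsd1 from 4723 ± 310 to 3279 ± 125 (-0.52 ± 0.04). All 3 targets were reduced in 3 of 3 libraries, Nsd1 and Whsc1 by less than Setd2. H3f3a changed by -0.37 and H3f3b by 0.14. Of the H3K36 methyltransferases tested 4 of 8 fell and none rose (adjusted p = 0.127). Cartilage genes fell for 23 of 25 and none rose (adjusted p = 1.46e-11, and adjusted p = 0.0364 with an estimated correlation). Col2a1 fell from 23861 ± 614 to 8076 ± 378 (log2 -1.56 ± 0.04, adjusted p = 1.32e-17), Sox9 from 7794 ± 233 to 3124 ± 131, Lect1, which encodes chondromodulin, from 3377 ± 148 to 660 ± 32.7, and Acan from 114 ± 8.51 to 5.90 ± 0.334.

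Cell cycle genes rose for 57 of 58 and none fell (adjusted p = 3.79e-30, and adjusted p = 0.143 with an estimated correlation). Mcm5, a subunit of the replicative helicase, rose from 1155 ± 43.5 to 3555 ± 147, Tpx2 from 2123 ± 83.6 to 5757 ± 78.2 and Kif23 from 637 ± 24.0 to 1839 ± 37.8. In H3.3 wild-type cells, whose libraries differ in their share of whole counts, these genes were at 3057 ± 173, 5812 ± 229 and 2138 ± 60.8. The control siRNA cells thus held the low levels, and HMT siRNA cells stood near the wild-type line for these 3 genes. Genes of the ATF4 and unfolded protein responses rose for 28 of 31 (adjusted p = 1.68e-10, and adjusted p = 0.143 with an estimated correlation). These included the serine synthesis gene Psat1 (log2 1.08), Shmt2 (1.12) and the amino acid transporter Slc7a5 (0.91). Cytokine and chemokine genes rose for 16 of 22 and fell for 3 (adjusted p = 0.000799, and adjusted p = 0.136 with an estimated correlation). Csf1 rose from 3199 ± 179 to 8210 ± 98.1 and Cxcl12 by log2 0.71, while complement C3 fell from 316 ± 51.3 to 36.3 ± 2.82. Interferon-stimulated genes rose for 22 of 37 and fell for 2 (adjusted p = 0.00637, and adjusted p = 0.143 with an estimated correlation).

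Lower in HMT siRNA cells were cholesterol synthesis genes, with 19 of 24 lower and 1 higher (adjusted p = 1.45e-05, and adjusted p = 0.143 with an estimated correlation). These included Nsdhl (log2 -0.63), Insig1 (-0.50) and Sc4mol (-0.47). Adipocyte genes fell for 12 of 21 and rose for 5 (adjusted p = 0.0281, and adjusted p = 0.22 with an estimated correlation). Cebpa went from 962 ± 40.3 to 287 ± 4.94, Plin4 at log2 -1.42 and Dgat2 at -1.59. Imprinted genes fell for 11 of 17 and rose for 1 (adjusted p = 0.0281, and adjusted p = 0.143 with an estimated correlation). These included Dlk1 (log2 -2.37) and Mest (-1.88). Wnt genes fell for 11 of 20 and rose for 4 (adjusted p = 0.04, and adjusted p = 0.143 with an estimated correlation). Without any 1 of 5 of the 6 siRNA libraries this list did not pass (adjusted p = 0.0579 to 0.0954). Sfrp1 was at log2 -1.59, Rspo3 at -1.76 and Rspo2 at -0.76. Ribosomal protein genes fell for 29 of 41 and 1 rose, by a small amount (median log2 -0.12; adjusted p = 0.0209, and adjusted p = 0.732 with an estimated correlation). That list did not pass without HMT replicate 3 (0.0631, with 18 lower and 1 higher) or control replicate 2 (0.124, with 21 lower and 5 higher). Histone genes fell for 12 of 30 and 1 rose (adjusted p = 0.0553; 0.0484 and 0.0474 without HMT or control replicate 3). Bone genes rose for 10 and fell for 7 of 20 (adjusted p = 0.312). Spp1 went from 3058 ± 64.2 to 33657 ± 734, Ank at log2 0.79 and Tnfrsf11b at -0.73. Hox genes fell for 3 and rose for 1 of 12 (adjusted p = 0.327). Hoxa4 was at log2 -0.86, Hoxa3 at -0.51 and Hoxa2 at -0.46. Developmental transcription factors rose for 12 and fell for 19 of 49 (adjusted p = 0.585). Sox6 was at -2.03 and Prrx1 at 0.40.

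The largest rises were Sprr1a, listed at 0 in control cells and at 234 ± 23.6 in HMT siRNA cells, and Styk1, from 6.97 ± 6.27 to 205 ± 3.12. Msln, which encodes mesothelin, rose from 10.0 to 139 ± 14.4, Unc13c from 11.4 to 151 ± 12.9 and Dmp1, an osteocyte matrix gene, from 11.6 to 125 ± 7.23. Sprr2k, Prl2c2 and Prl2c3 share reads with near copies. The largest falls included Cmtm5 (log2 -4.19), Cldn19 (-4.04), Fmod, which encodes fibromodulin (-3.95), Bmx (-3.81), Sfrp2 (-3.70), Ang2 (-3.64) and Angptl1 (-3.64). In all, 8262 of 12634 genes tested changed (4117 higher, 4145 lower), 1216 of them by at least 2-fold (608 higher, 608 lower).

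The 2 responses share no library, and they were set against each other to ask how far the enzyme knockdown gives the changes seen with the mutant histone. Of the 1077 genes at least 2-fold lower in H3.3K36M cells, 75.4% were also lower in HMT siRNA cells (31.7% of all genes were), with median log2 -1.81 in the former and -0.75 in the latter. Of the 1614 genes at least 2-fold higher in H3.3K36M cells, 42.7% were higher in HMT siRNA cells, against 31.9% of all genes, and 11.5% were lower (medians 2.20 and 0.42). At 2-fold in both, 402 genes were lower in both (52.3 would be shared by independent lists) and 361 higher in both (85.6), whereas 76 and 17 moved in opposite directions (78.3 and 57.1). Across the 13186 genes tested in the 10-library fit, Pearson's r of the log2 fold changes was 0.519 and Spearman's rho 0.537; genes are not independent replicates. Other divisions of the 6 siRNA libraries gave an absolute r of 0.345 to 0.417, but each still sets more HMT than control libraries on 1 side, so these give no level for unrelated responses.

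The difference between the responses was tested gene by gene. Cartilage genes had the larger fold changes in H3.3K36M cells, with 21 of 26 lower and none higher in the difference (22 adjusted over the list alone; adjusted p = 8.62e-11, and adjusted p = 0.0407 with an estimated correlation). The references differed at the start: Col2a1 was at 74086 ± 1596 in wild-type and 23861 ± 614 in control siRNA cells, and ended at 6483 ± 314 in H3.3K36M and 8076 ± 378 in HMT siRNA cells. Cell cycle genes had the smaller rises in H3.3K36M cells, with 52 of 58 lower and none higher (adjusted p = 4.28e-19, and adjusted p = 0.297 with an estimated correlation). Here too the references differed. Mcm5 was at 3057 ± 173 in wild-type and 1155 ± 43.5 in control siRNA cells. It ended at 5354.5 ± 198 in H3.3K36M and 3555 ± 147 in HMT siRNA cells, so the smaller rise was not a lower level. Ribosomal protein genes were higher for 38 of 41 (adjusted p = 1.35e-14, and adjusted p = 0.361 with an estimated correlation). Smooth muscle genes were higher for 12 of 14 (adjusted p = 5.28e-05, and adjusted p = 0.0768 with an estimated correlation). Matrix genes were higher for 17 and lower for 37 of 61 (adjusted p = 5.28e-05, and adjusted p = 0.299 with an estimated correlation). Bone genes were lower for 13 and higher for 2 of 20 (adjusted p = 0.00033, and adjusted p = 0.0768 with an estimated correlation). Cholesterol synthesis genes were higher for 15 and lower for 2 of 24 (adjusted p = 0.00633, and adjusted p = 0.299 with an estimated correlation). Wnt genes were higher for 16 and lower for 3 of 23 (adjusted p = 0.00784, and adjusted p = 0.107 with an estimated correlation). Skeletal muscle genes were higher for 6 of 10 (adjusted p = 0.0342, and adjusted p = 0.215 with an estimated correlation; 0.0923 without wild-type and 0.0792 without H3.3K36M replicate 1). After quantile normalisation smooth muscle genes were higher for 9 and lower for 1, and skeletal muscle genes higher for 4 and lower for 1.

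Genes with the largest excess in H3.3K36M cells were Igfbp5, at 5.87 ± 8.30 in wild-type and 345 ± 20.8 in H3.3K36M cells but 1582 ± 158 in control and 287 ± 27.1 in HMT siRNA cells. Next were Add2 (2.56 to 454 with the mutant, 3.42 to 1.24 with the siRNAs), Pof1b, F13a1, Klhl13 and Asxl3. The largest deficits were in Cytl1 (4097 to 9.85 with the mutant, 1432 to 990 with the siRNAs), Zcchc5, Eln, Sorbs2, Nog, which encodes the BMP antagonist noggin, and Has2. Nog was at 229 ± 27.7 in wild-type cells and listed at 0 in both siRNA groups, so these differences carry a difference between the wild-type line and the siRNA cells. The difference changed 7238 of 13186 genes (3626 higher, 3612 lower), 2063 by at least 2-fold (1304 higher, 759 lower). After quantile normalisation the latter were 1045 higher and 1149 lower, and with no filter 1933 and 851. Nsd1, Whsc1 and Setd2 differed by log2 0.63, 1.66 and 1.30, and H3f3a and H3f3b by -0.40 for both.

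**Figure D2:**
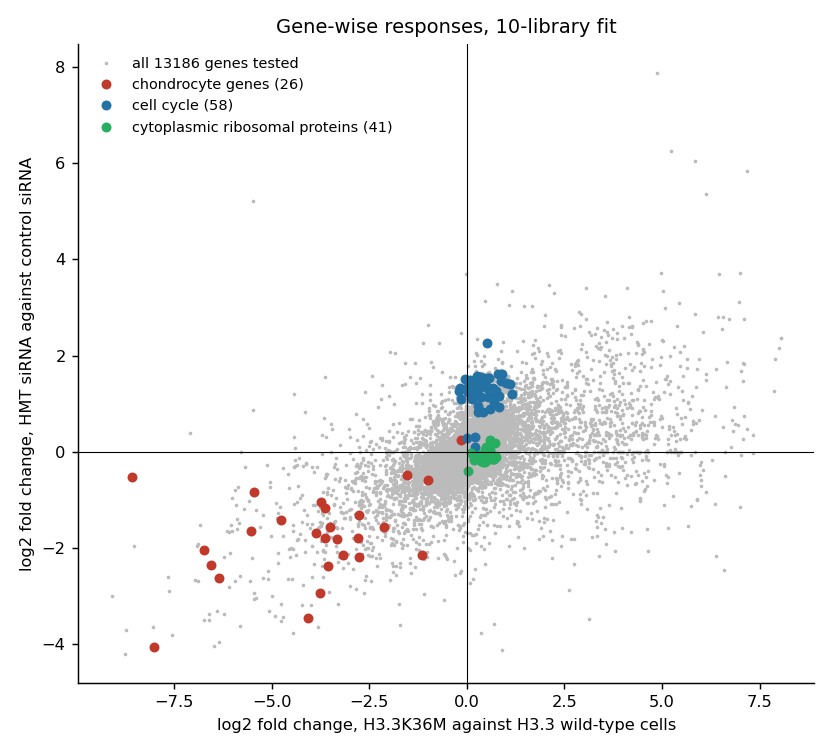
Log2 fold change in HMT siRNA against control siRNA cells (vertical axis) and in H3.3K36M against H3.3 wild-type cells (horizontal axis), 1 point per gene, for 13186 genes with the cartilage, cell cycle and ribosomal protein lists colored. Cartilage genes lie low on both axes and cell cycle genes high on the vertical axis; r was 0.519 over all genes.

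H3.1K36M cells were set against H3.3 wild-type cells to ask whether the substitution on the other histone H3 variant goes with the same genes; an H3.1 wild-type line was not analysed here. Cartilage genes fell for 24 of 24 (adjusted p = 6.45e-12, and adjusted p = 0.176 with an estimated correlation). Col2a1 was at 99987 ± 1722 in wild-type and 11226 ± 9.09 in H3.1K36M cells, Col11a1 at log2 -5.46, Matn4 at -4.81 and Sox6 at -8.95. Ribosomal protein genes rose for 41 of 41 (adjusted p = 1.13e-11, and adjusted p = 0.357 with an estimated correlation). Rps2 was at log2 0.88, Rpl26 at 0.95 and Rpl5 at 0.81. ATF4 and unfolded protein response genes rose for 26 of 32 and fell for 4 (adjusted p = 3.08e-05, and adjusted p = 0.387 with an estimated correlation). Chac1 was at log2 2.16, Ddit3 at 1.45 and Atf4 at 1.01. Matrix genes fell for 41 and rose for 16 of 60 (adjusted p = 3.08e-05, and adjusted p = 0.357 with an estimated correlation). Col8a1 was at log2 -5.55 and Thbs1 at -2.91 but Thbs2 at 3.39. Cholesterol synthesis genes rose for 20 of 24 and 1 fell (adjusted p = 0.000219, and adjusted p = 0.357 with an estimated correlation). Fdps was at log2 0.80 and Lss at 0.86.

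Smooth muscle genes rose for 10 and fell for 3 of 14 (adjusted p = 0.00785, and adjusted p = 0.357 with an estimated correlation). Histone genes fell for 21 of 36 and 1 rose (adjusted p = 0.00568, and adjusted p = 0.357 with an estimated correlation). H3K36 demethylases and readers fell for 11 of 16 and 1 rose (adjusted p = 0.0253, and adjusted p = 0.407 with an estimated correlation). Macrophage markers rose for 8 of 11 (adjusted p = 0.0342, and adjusted p = 0.504 with an estimated correlation). The list did not pass less C1qa, C1qb and C1qc, with 5 of 8 higher (adjusted p = 0.1), nor without wild-type or H3.1K36M replicate 2 (0.0533 and 0.0813). The macrophage markers C1qa, C1qb and C1qc were at 32.7 ± 14.7, 16.6 ± 7.69 and 15.9 ± 4.67 in H3.1K36M cells and listed at 0 in the wild-type and H3.3K36M libraries. Of 109 genes abundant in tumors and nearly absent from H3.3 cells (at most 3 estimated reads per library), 41 were above 0 in both H3.1K36M libraries. The 2 bounds differ, so this count has no like baseline. Whether the C1q reads come from these cells was not settled. Cell cycle genes rose for 18 and fell for 28 of 58 (47 adjusted over the list alone; adjusted p = 0.241). Fat genes fell for 13 and rose for 5 of 22 (adjusted p = 0.207; Dgat2 -4.58, Cebpa -3.91, Angptl4 3.54). Bone genes fell for 13 and rose for 6 of 21 (adjusted p = 0.125; Enpp1 -4.27, Postn -1.60, Omd -1.36). Hox genes rose for 8 and fell for 8 of 18 (adjusted p = 0.88; Hoxb9 4.72, Hoxc13 -5.04, Hoxa3 -1.84). Developmental transcription factors rose for 21 and fell for 26 of 55 (adjusted p = 0.642; Osr2 2.51, Msx1 -2.31). Wnt genes rose for 15 and fell for 6 of 25 (adjusted p = 0.298; Notum 2.48, Rspo2 -2.52).

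The largest rises were Itih2, from 8.29 ± 1.51 to 3860 ± 37.7, and Arhgap36, from 2.11 ± 1.10 to 1144 ± 9.39. Prl2c3 and Rps27 are uncertain because of shared reads. The largest falls were Eln, by log2 -11.64, Sfrp2, from 6093 ± 29.6 to 1.66 ± 0.369, Gas7, from 8733 ± 191 to 3.53 ± 0.927, and Cytl1, from 5530 ± 139 to listed at 0. Whsc1 rose by log2 0.79 and Nsd1 by 0.21, Setd2 changed by -0.39, H3f3a by -0.94 and H3f3b by -0.75. In all, 10652 of 13404 genes tested changed (5510 higher, 5142 lower), 3320 of them by at least 2-fold (1685 higher, 1635 lower). The share of whole counts among genes with 1 to 20 estimated reads was 76.8 to 79.1% in the 4 H3.3 cell libraries and 84.2 to 86.8% in the other 14. Among genes counted whole in each library, 25.5% were at least 2-fold lower in H3.1K36M than in wild-type cells and 31.1% higher, against 25.9% and 29.1% of other genes of like level. In tumors against cells these shares were 21.5% lower and 40.4% higher, against 30.1% and 31.6%. For H3.3K36M against wild-type cells, which do not differ in the share of whole counts, they were 17.3% lower and 35.9% higher, against 12.1% and 37.5%. Other effects of a library set coincide with the group and cannot be told apart from it in the comparisons of H3.1K36M cells or tumors with H3.3 libraries.

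In the direct comparison with H3.3K36M cells, the cell cycle genes stood lower in H3.1K36M cells for 50 of 58 and higher for 5 (adjusted p = 2.5e-12, and adjusted p = 0.491 with an estimated correlation). Top2a was at 35591 ± 490 and 19230 ± 5.09 and Prc1 at log2 -0.82. Cholesterol synthesis genes were higher for 18 and lower for 1 of 24 (adjusted p = 3.27e-06, and adjusted p = 0.412 with an estimated correlation). Hsd17b7 was at log2 1.16, Sc4mol at 0.93 and Lss at 0.98. Cartilage genes were lower for 18 and higher for 3 of 24 (adjusted p = 0.000305, and adjusted p = 0.412 with an estimated correlation). Col9a1 went from 173 ± 15.1 to 11.7 ± 0.255 and Prg4, which encodes lubricin, at log2 -3.15. After quantile normalisation 13 cartilage genes were lower and 3 higher. Endothelial markers were lower for 12 of 15 (adjusted p = 0.000804, and adjusted p = 0.412 with an estimated correlation). Flt1 was at log2 -1.25, Tek at -1.14 and Eng at -0.59. Ribosomal protein genes were higher for 32 and lower for 3 of 41 (adjusted p = 0.000305, and adjusted p = 0.515 with an estimated correlation). They were 15 higher and 10 lower after quantile normalisation, where Rps2 went from 0.33 to -0.04; Rpl8 was at 0.44.

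Interferon-stimulated genes were lower for 25 and higher for 3 of 39 (adjusted p = 0.000892, and adjusted p = 0.491 with an estimated correlation). The p53 targets and cell cycle inhibitors were higher for 15 and lower for 3 of 21 (adjusted p = 0.000892, and adjusted p = 0.412 with an estimated correlation). Glycolysis and hypoxia genes were higher for 23 and lower for 5 of 35 (adjusted p = 0.000892, and adjusted p = 0.442 with an estimated correlation). ATF4 and unfolded protein response genes were higher for 22 and lower for 6 of 32 (adjusted p = 0.00356, and adjusted p = 0.515 with an estimated correlation). Matrix genes were lower for 37 and higher for 18 of 60 (adjusted p = 0.0207, and adjusted p = 0.491 with an estimated correlation). Fat genes Acsl1 (1.18), Scd1 (0.70) and Pparg (1.29) were higher within a list that did not pass (7 higher and 10 lower of 22, adjusted p = 0.48). Bone genes were higher for 7 and lower for 9 of 21 (7 and 7 after quantile normalisation; adjusted p = 0.901; Tnfrsf11b 3.84, Postn 1.81, Spp1 -1.80). Hox genes were higher for 1 and lower for 7 of 18 (adjusted p = 0.218; Hoxb9 -2.54, Hoxc6 -1.73, Hoxc9 -2.99; 5 higher and 6 lower after quantile normalisation). Developmental factors were higher for 14 and lower for 23 of 55 (adjusted p = 0.274; Foxc2 0.79, Osr2 -1.01). Wnt genes were higher for 7 and lower for 11 of 25 (adjusted p = 0.351; Rspo3 -3.57, Notum -1.84, Dkk3 -2.95).

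The genes largest in the direct comparison were Prl4a1, listed at 0 in H3.3K36M and at 126 ± 5.82 in H3.1K36M cells, Theg, Serpinb2, Arhgef5, Stmn2 and Ppfibp2 on the higher side. Those on the lower side were Tnmd (1962 ± 84.5 to 9.03 ± 5.99), Efemp1 (3222 ± 166 to 17.9 ± 6.30), Asxl3, Dlk1, Crym and Psca. Rps27, Sprr2a2 and H2-Q7 are uncertain because of shared reads. Whsc1 stood at log2 -0.25, Setd2 at -0.14, Nsd1 at 0.13, H3f3a at -0.14 and H3f3b at -0.47. In all, 9141 of 13404 genes differed (4741 higher, 4400 lower), 1762 of them by at least 2-fold (375 higher, 1387 lower); after quantile normalisation the latter were 753 and 941, and with no filter 457 and 1941.

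The 2 mutant lines were set side by side against the same wild-type libraries. At 2-fold or more, 1224 genes were higher in both (221 would be shared by independent lists), 968 lower in both (139.9) and 36 opposite. Pearson's r of the fold changes across genes was 0.836 and Spearman's rho 0.771. Simulated unchanged groups sharing the wild-type libraries gave r 0.504 and covariance 0.0235, against an observed covariance of 1.82 (difference 1.79, 100 simulations). With 1 wild-type library for H3.3K36M and the other for H3.1K36M, a division made after the data were seen, r was 0.810 either way. At 2-fold or more 1184 and 1188 genes were then higher in both (219 and 220 for independent lists), 940 and 948 lower in both (140 either way) and 53 and 54 opposite. Both wild-type libraries still come from 1 line, whose own state the comparisons share.

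Tumors were compared with the H3.3K36M cells they came from to describe how expression differs after growth in the animal. Markers of blood and vessel cells were high. Levels in host cells were not measured, so a rise in any list or gene below may lie in host cells, in the H3.3K36M cells or in both. The macrophage markers rose for 24 of 24 (adjusted p = 5.86e-15, and adjusted p = 0.0579 with an estimated correlation). C1qa, C1qb and C1qc, listed at 0 in the cells, reached 74870 ± 15859, 54921 ± 10125 and 51969 ± 8755. Ctss rose from 2.21 ± 1.78 to 27520 ± 1779 and Msr1 from 2.11 ± 0.292 to 5961 ± 640. Endothelial markers rose for 24 of 26 and 1 fell (adjusted p = 2.58e-08, and adjusted p = 0.299 with an estimated correlation). Esam was at log2 8.73, Ecscr at 6.37 and Emcn at 8.34. Lymphocyte and NK markers rose for 18 of 19 and 1 fell (adjusted p = 2.78e-06, and adjusted p = 0.501 with an estimated correlation). Klrk1 was at log2 7.26, Cd79b at 8.05 and Ncr1, an NK cell receptor, at 322 ± 125 and listed at 0 in the cells. Granzymes Gzmd and Gzmg, near copies, reached 10677 ± 4782 and 10479 ± 5792.

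Neutrophil markers rose for 7 of 9 (adjusted p = 0.0121, and adjusted p = 0.502 with an estimated correlation). These included Csf3r (log2 7.33) and Il1r2 (5.85). S100a9 was at 177 ± 66.1. Red cell markers rose for 5 of 6 (adjusted p = 0.025, and adjusted p = 0.501 with an estimated correlation; adjusted p = 0.0527 without tumor 6 and 0.058 without H3.3K36M cell replicate 2). Alas2 was at log2 4.61, Hbb-b1 at 1456 ± 530 and Hba-a2 at 974 ± 717. Pericyte markers rose for 8 and fell for 3 of 12 (adjusted p = 0.0951). Mcam was at log2 3.60, Kcnj8 at 4.59 and Higd1b at 89.7 ± 21.3. Mast cell markers rose for 7 and fell for 1 of 10 (9 adjusted over the list alone; adjusted p = 0.0676). Kit was at 163 ± 38.3, Cpa3 at log2 7.68 and Tpsb2 at 8.42. Schwann cell and nerve markers rose for 6 and fell for 2 of 11 (adjusted p = 0.447). Mbp was at log2 3.40, Prph at 2.51 and Tubb3 at -2.08. Keratinocyte markers rose for 11 and fell for 1 of 23 (adjusted p = 0.289; 7 and 2 after quantile normalisation). Krt8 was at log2 2.35, Epcam at 110 ± 100.1 and Cdh1 at -1.90. Skeletal muscle genes rose for 14 of 20 (10 after quantile normalisation; adjusted p = 0.0336, and adjusted p = 0.678 with an estimated correlation).

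Some markers differed between tumors. Krt5 stood at 8880, 3090, 5092, 58.7, 10270 and 21.8 in tumors 1 to 6, the muscle gene Ckm at 94.5, 99.5, 70.7, 58.7, 1210 and 3705, and the milk protein gene Csn2 at 7.38, 0, 106.1, 3.04, 4382 and 1669. Interferon-stimulated genes rose for 43 of 45 (44 adjusted over the list alone; adjusted p = 5.86e-15, and adjusted p = 0.502 with an estimated correlation). Psmb8 went from 66.5 ± 4.07 to 16341 ± 1845, Zbp1 at log2 7.19 and Trim25 at 9.08. Cytokine and chemokine genes rose for 25 and fell for 6 of 36 (adjusted p = 0.000937, and adjusted p = 0.299 with an estimated correlation). Glycolysis and hypoxia genes rose for 29 of 38 and 1 fell (adjusted p = 0.00144, and adjusted p = 0.678 with an estimated correlation). Egln3 was at log2 7.24, Slc2a3 at 6.09 and Car9 at 5.39. Ribosomal protein genes rose for 41 of 41, 33 of 41 after quantile normalisation (adjusted p = 1.58e-05, and adjusted p = 0.678 with an estimated correlation).

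Among the largest falls in tumors, Lox, which encodes lysyl oxidase, fell from 89789 ± 1394 to 462 ± 156, Slc1a3 from 3892 ± 116 to 17.7 ± 12.3, Smoc2 from 16977 ± 402 to 99.5 ± 70.4. Hs6st2 fell from 3548 ± 59.6 to 6.74 ± 5.06, Tnmd to 4.66 ± 3.84, Pcdh11x to 1.53 ± 0.937 and Rspo2 from 1364 ± 15.2 to 3.20 ± 2.80. Tgoln2, expressed by nearly all cells, was listed at 0 in the tumors, so a 0 here need not mean that a gene is silent. Cholesterol synthesis genes fell for 20 of 24 and none rose (adjusted p = 1.18e-07, and adjusted p = 0.501 with an estimated correlation). Sc5d was at log2 -2.64, Insig1 at -2.76 and Fdft1 at -1.65. Cell cycle genes fell for 43 and rose for 6 of 58 (51 adjusted over the list alone; adjusted p = 2.78e-06, and adjusted p = 0.678 with an estimated correlation). H3K36 methyltransferases fell for 6 of 8 (adjusted p = 0.0336, and adjusted p = 0.517 with an estimated correlation). Setd2 was at log2 -1.29 ± 0.16, Whsc1 at -0.77 ± 0.15 and Nsd1 at -0.71 ± 0.12. H3f3b rose by 0.75 and H3f3a did not pass (0.07 ± 0.09, adjusted p = 0.5).

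Cartilage genes rose for 8 and fell for 8 of 24 (adjusted p = 0.568), Col2a1 from 8552 ± 407 to 193 ± 60.9, Col11a1 by log2 -6.91 and Chst11 by 1.62. After quantile normalisation 3 were higher and 10 lower. Wnt genes rose for 15 and fell for 9 of 31 (adjusted p = 0.356; 11 and 10 after quantile normalisation). The ligand Wnt7b went from 71.0 ± 5.06 to 8170 ± 1488, Tcf7 at log2 3.47 and Axin2 at 3.29. Fat genes rose for 15 and fell for 7 of 32 (adjusted p = 0.447; 10 and 8 after quantile normalisation). Cebpa was at log2 2.78, the fatty acid receptor Cd36 at 7.02 and Acaca at -2.21. The mean log2 level of the fat list differed between tumors, from 6.62 in tumor 4 to 8.82 in tumor 5. Bone genes rose for 9 and fell for 8 of 23 (adjusted p = 0.526; 7 and 13 after quantile normalisation), with Col1a1 from 335380 ± 28918 to 72522 ± 8666, Enpp1 at log2 2.80 and Bmp2 at 70.7 ± 20.9. Hox genes rose for 10 and fell for 4 of 27 (adjusted p = 0.526; 7 and 10 after quantile normalisation), with Hoxd9 at log2 5.27, Hoxd8 at 4.74 and Hoxb9 at -3.52. Developmental transcription factors fell for 29 and rose for 14 of 58 (adjusted p = 0.0951). Prrx1 was at log2 -2.31, Meox1 at 5.48 and the endothelial factor Sox17 at 111 ± 17.5. Fcrls and Tyrobp, myeloid genes, were at 8233 ± 1872 and 12108 ± 2140. In all, 11163 of 14842 genes tested changed (6086 higher, 5077 lower), 6997 of them by at least 2-fold (3930 higher, 3067 lower; 2944 and 3879 after quantile normalisation, 4134 and 3576 with no filter). The median log2 fold change of all genes was 0.14 as scaled by the authors and -0.12 after quantile normalisation, so small changes are relative to it.

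**Figure D3:**
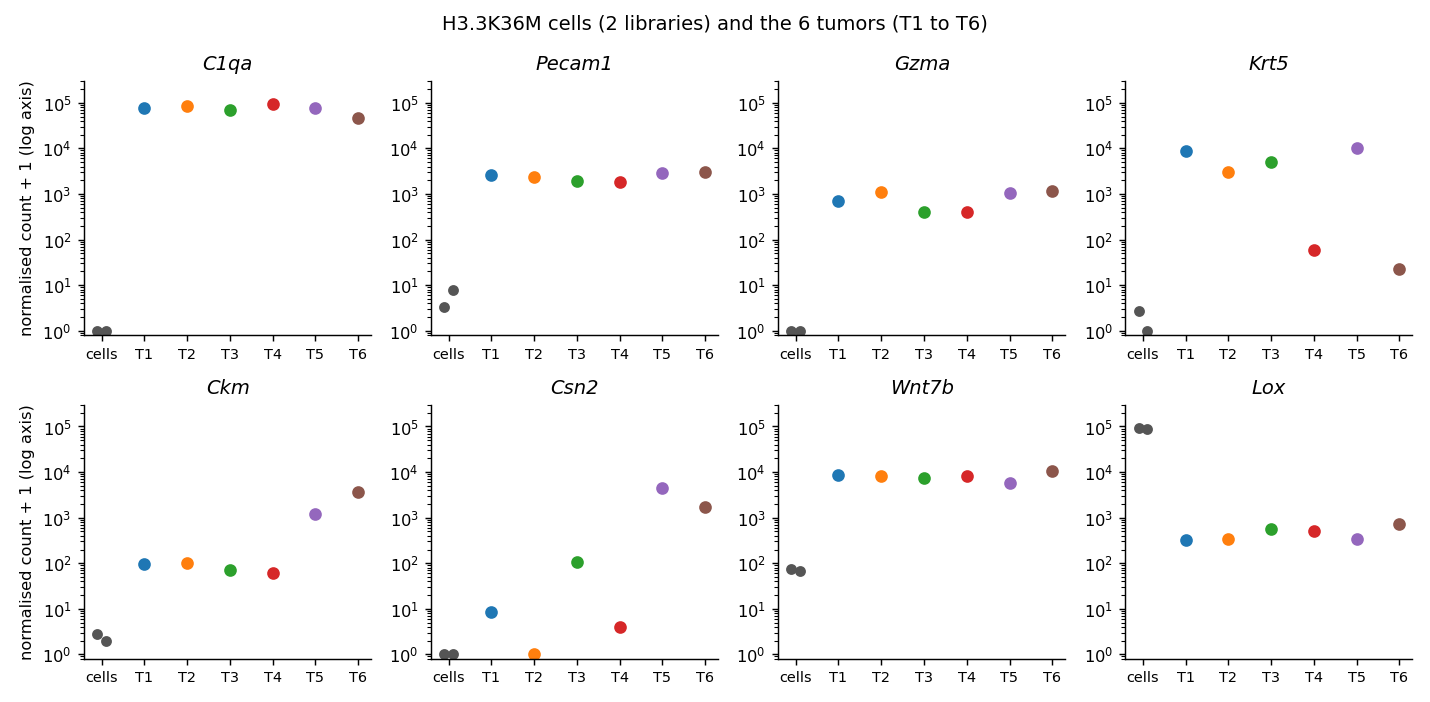
Normalised counts plus 1 (log axis) of 8 genes in both H3.3K36M cell libraries (gray) and in each of the 6 tumors, T1 to T6 (colors). C1qa, Pecam1, Gzma and Wnt7b were high in all 6 tumors and Lox was low in all 6, while Krt5 ranged from 21.8 to 10270, Ckm from 58.7 to 3705 and Csn2 from 0 to 4382.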

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

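The tests on the drift of the H3.3K36M line and of both lines, on Mtap and Cdkn2a and on dilution by host cells, and the count of splits at 2-fold, were chosen only after the results were seen; the tests on drift of the wild-type line alone and on the sequencing of tumors were written before.

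In 103 groups of 6 tumors 8 had a tumor far from the others by Dixon's criterion, where chance gives about 1 in 20. H3f3a was at 12350 in tumor 2 (13660 to 14490 in the others), Pcdh11x was at 0 in tumor 4 (1.34 to 2.71), Hoxb9 at 99.8 in tumor 6 (46.6 to 61.5), Ecscr at 910.6 in tumor 6 (1236 to 1385), Mcam at 1672 in tumor 4 (2068 to 2345) and S100a9 at 307.8 in tumor 1 (120.2 to 166.0). The mean log2 level of H3K36 methyltransferases was 10.8 in tumor 6 (10.3 to 10.4) and that of glycolysis and hypoxia genes 11.5 in tumor 5 (12.2 to 12.4).

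The fold changes of H3.1K36M and of H3.3K36M cells, each against wild-type cells, went opposite ways for 8 named genes, each tested as a difference with limma. All 8 were named for being among the smallest adjusted p of their lists in that same direct comparison, so the test gives no separate support. Among the 13404 genes tested, 905 had opposite calls. Each mutant is a single line, so these are differences between lines. Rspo3 was at log2 1.92 in H3.3K36M and -1.64 in H3.1K36M cells (difference -3.57), Dkk3 at 0.96 and -1.99 (-2.95), Flt1 at 0.75 and -0.51 (-1.25), Birc5 at 0.48 and -0.53 (-1.003), Hsd17b7 at -0.86 and 0.30 (1.16), Acsl1 at -0.33 and 0.85 (1.18), Lss at -0.12 and 0.86 (0.98) and Sc4mol at -0.18 and 0.75 (0.93).

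H3.3K36M and wild-type cells are 1 line each, and lines of this kind may differ for reasons other than the histone. If the wild-type line alone had drifted, fewer than 50 percent of its 2-fold differences would return against control siRNA cells, and 69 percent of 2690 genes did (72 opposite); if the H3.3K36M line alone had drifted, fewer than 50 percent would return in H3.1K36M against wild-type cells, and 74.9 percent of 2816 did (38 opposite). Each of these tests keeps 1 of the lines and sets libraries with other shares of whole counts against each other, and 51.7 percent of 2690 genes (1392) held in both. H3.1K36M against control siRNA cells, on a common scale, shares no library with the pattern and has 1 share of whole counts: 64.3 percent of 2426 genes returned at 2-fold and 4.58 percent were opposite, where independent lists would give 11 and 10.9 percent. These values argue against drift of the H3.3 lines, alone or together, for the genes that returned; the rest stay open, as does a state both K36M lines share for another reason, and an effect of the substitution is a hypothesis found on these data.

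Cdkn2a and Cdkn2b, neighboring cell cycle inhibitor genes, were near 0 in every histone line and present in both siRNA groups; they were named after their values were seen. On a common scale set across tables through the 4 shared libraries (ratios of 1.318 to 1.354), Cdkn2a was at 0.722 in wild-type, 0.578 in H3.3K36M, 9.07 in H3.1K36M, 252 in control and 428 in HMT siRNA cells, and Cdkn2b at 8.45, 1.45, 5.32, 325 and 325; tumors held 82.9 and 58.3. A sequencing difference of the H3.3 libraries is argued against, since H3.1K36M libraries, which share the whole-count share of the siRNA libraries, held 3.6 percent of the control level of Cdkn2a. Loss of a stretch that reaches the neighbor Mtap is argued against in both K36M lines, where Mtap was at 120 percent of control or more, while in the wild-type line Mtap was at 44 percent and the question stays open. A smaller loss or silencing remains possible in the lines and was not tested; the 2 Mtap tests were parted after the first result was seen.

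Many genes of H3.3K36M cells were lower in tumors. Of 3067 genes at least 2-fold lower, 1256 were more than 4-fold and 250 more than 16-fold lower, and 51.8 percent of the 6190 genes most expressed in the cells were not lower. Dilution by host cells stays open as a cause: the middle of the log2 fold changes spanned 1.29, but the bound set for this value took host cells to lack these genes, and the levels in host cells were not measured. Among genes counted whole in every library, 21.5 percent were at least 2-fold lower, against 30.1 percent of other genes of like level (a ratio of 1.4). In H3.3K36M against wild-type cells, which do not differ in the share of whole counts, these were 17.3 and 12.1 percent. The 2 sets of genes thus also differ without a sequencing difference, and the ratio alone does not mark one. The sequencing difference and the group cannot be told apart for part of the pattern, since the groups coincide with it. Growth in the animal is a biological difference the design names and stays untested as a cause.

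The 6 siRNA libraries make 10 splits, too few for a share under 0.05; 1 of the 10 splits, the real one, gave as many changed genes (8262), and the highest other gave 0 by limma, with 98 to 367 genes at an unadjusted p under 0.05. At 2-fold or more the real split gave 1216 and the highest other 0, so 1 of 10 splits again. Every other split mixes HMT and control libraries within a side, which adds their difference to the spread. The low counts of these splits therefore give no level for unrelated groups.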

How the results depend on the processing

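Voom, the control siRNA reference, the 2-fold counts, the parted wild-type libraries, the list less C1q genes and the lists without single libraries were chosen after seeing the data; all other alternatives were planned. Every total of changed genes, and of those at 2-fold, stayed within 1.5 times its value in every setting run. The sides at 2-fold moved more: H3.1K36M against H3.3K36M went from 375 to 753 higher and the difference from 759 to 1149 lower after quantile normalisation, and H3.3K36M from 1690 to 2566 higher with no filter. Over alternatives with 1 library left out, changed genes ranged from 8369 to 9677 for H3.3K36M, 7717 to 8291 for HMT siRNA, 6326 to 7376 for the difference of responses, 9838 to 10424 for H3.1K36M against wild type, 7861 to 8336 for H3.1K36M against H3.3K36M and 9131 to 12079 for tumors. Where this leaves 1 library in a group, it is assumed to vary like the others. Voom called 9943, 8136, 7535, 10550, 9557 and 11201 genes in the same order. The control siRNA reference, which crosses library sets, gave 9965 genes for H3.3K36M, 2981 at 2-fold. The numbers shared by HMT and control libraries were not taken to pair them. Correlations of deviations were 0.096, 0.046 and 0.095, where all over 0.1 would be needed, and -0.139 to 0.059 for other pairs. The values of same-numbered libraries were all above 0, so a weak pairing is not excluded. With the replicate block the counts were 9710, 8408, 7461, 10604, 9075 and 12437. The count test planned for tables of raw or expected counts was not run, because only 35.2 to 56.1% of values were whole counts. The plan named no such condition, so this choice departs from it.

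Lists past the threshold went from 10, 10, 9, 9, 10 and 13 (H3.3K36M, HMT siRNA, difference, H3.1K36M against wild type, H3.1K36M against H3.3K36M, tumors) to 0, 1, 1, 0, 0 and 0 with an estimated correlation. That form of the test also used only the 2, 6, 6, 3, 3 and 6 residual degrees of freedom of the fits. The loss of lists therefore cannot be laid to correlation alone. Without single libraries, 7 to 12, 8 to 10, 8 to 9, 8 to 10, 10 and 12 to 13 passed in the same order, and 8 for H3.1K36M against wild type less the C1q genes. The correlation of H3.3K36M and HMT siRNA responses (0.519) was 0.536 with pseudocount 8, 0.461 with no filter and 0.502 to 0.522 with a library left out. That of H3.1K36M and H3.3K36M (0.836) was 0.811 with no filter, 0.821 after quantile normalisation, 0.810 with 1 wild-type library for each line, either way (0.8099 and 0.8097), and 0.825 to 0.836 with a library left out. The cause was not tested.

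Over the 280 named values and the settings run, 4265 kept direction and call, 16 lost the call, 3 gained it and 10 turned. With the control siRNA reference the turned values for H3.3K36M were Nsd1 -0.0528, H3f3b 0.22, Hoxc13 3.25, Rps20 -0.15, Hist1h1c 0.15 and Hist1h4i 1.61. Rps2 in H3.1K36M against H3.3K36M was -0.0353 after quantile normalisation. H3f3a in tumors, whose change did not pass, was -0.0067 with TMM scaling, -0.0286 after quantile normalisation and -0.0133 with the replicate block. The cause was not tested. In simulated data 1.5-fold changes were recovered for 92% of genes in H3.3K36M cells and for 30% in tumors, whose libraries varied more (dispersion 0.000267 and 0.0202). These rates are for whole counts with 1 dispersion for all genes and may not carry over to the real values. At these depths genes at a few estimated reads are imprecise.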

Other observations

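Genes that switch between low (under 10 in every library of 1 group) and clear levels (at least 50 in every library of the other) were counted under a rule chosen after the data were seen. In H3.3K36M cells 172 genes were on and 51 off against wild type, in H3.1K36M cells 127 on and 133 off, in HMT siRNA cells 3 on and 8 off, and in tumors 501 on and 54 off. The tables were scaled separately, so these bounds are not the same level in each. In the siRNA table, which gave the HMT counts, H3.3K36M cells had 157 on and 65 off. The siRNA groups also had to meet the bounds in 3 libraries each, against 2 for the histone lines. Wild-type cells and control siRNA cells, whose libraries also differ in their share of whole counts, had 29 on and 20 off. In the siRNA table Col2a1 was at 74086 ± 1596 in wild-type cells and 23861 ± 614 in control siRNA cells, Igfbp5 at 5.87 ± 8.30 and 1582 ± 158, and Nog at 229 ± 27.7 and listed at 0.

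Tumors 5 and 6 held transcripts of genes typical of mammary tissue: Wap was at 2829 and 160.6, Glycam1 at 1780 and 837.3 and Csn2 at 4382 and 1669, against 0 to 106.1 for Csn2 in the other 4. Muscle Acta1 was at 2360 and 6745 in these 2 and 329.1 to 620.2 in the others. Tumor 6 correlated with the other tumors at 0.977 to 0.982, and each of the others reached at least 0.99 with another tumor. Apoe was at 43760 to 169100 in the tumors and Cd3e at 0 to 0.671, in mice labelled athymic.

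C1qa was at 22.3 and 43.1, C1qb at 11.2 and 22.0 and C1qc at 12.6 and 19.2 in the H3.1K36M libraries, and these genes were listed at 0 in the wild-type, H3.3K36M and siRNA libraries. Of 109 genes abundant in tumors and nearly absent from the H3.3 cells, 41 were detected in both H3.1K36M libraries. Nearly absent allowed up to 3 estimated reads per H3.3 library, while detected meant any value above 0. The H3.3 and siRNA libraries were not counted by the latter rule, so the 41 have no baseline. Levels of the 109 genes, in ppm of the tumor mean, had a median of 458.7 (quartiles 127.5 and 863.6), and 5 macrophage genes summed to 256.7 and 469.1 ppm in the 2 libraries. The 6 keratinocyte, muscle and red cell genes held 3 reads in all, and 3 lymphocyte and NK genes held 1 and 7. A test on the 6 genes, run after the values were seen, was set aside for its few reads, and whether RNA of tumors is present in these libraries was not settled.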
